A study of Mus musculus with 12 samples.

How the data were processed

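Gene values of 12 perfused lungs taken after death from male C57BL/6 mice were used, 6 from survivors of cecal ligation and puncture (CLP) at 21 days and 6 from unoperated mice, per the labels. Libraries were made with a 3' mRNA kit that had a module for unique molecular identifiers. The submitters' processing notes name FastQC, Trim Galore 0.5.0, STAR 2.6.0, featureCounts, DESeq2 1.22.2 and the mouse genome build GRCm38. Whether the molecular identifiers were used to collapse copies, and the annotation release, are not stated.

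The deposited table holds 20858 gene symbols, each with values on a log2-like scale after size factor scaling and a variance-stabilising transformation (VST) by the authors. The lowest value, 5.49, is the same in all 12 libraries and stands for 0 reads. Inverting the transformation gave a whole number of reads, within 0.001, in 100% of the values. These recovered reads gave the depth of each library (3098945 to 5563531 reads) and the normalised reads printed beside each difference. The transformation compresses low values: a doubling is a difference of 0.23 at 10 normalised reads, 0.60 at 100 and 0.92 at 1000. Folds were therefore taken from the means of normalised reads, and differences and tests from the VST values. The lowest total of a gene over the 12 libraries was 10 reads, and 6805 genes had under 10 normalised reads on average. Copies made by PCR are not independent molecules, so bounds against 0 reads cover counting error only. Gene positions came from GENCODE M21 by symbol, which matched 20399 symbols (97.8%).

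Groups were compared with limma 3.58.1 in R 4.3.3 (linear model, moderated test with a mean-variance trend, 2-sided, no covariate), and Benjamini-Hochberg adjustment covered all 20858 genes at a threshold of 0.05. The labels give no batch, pairing or collection time, so no such term was fitted. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 48 lists of at least 5 measured genes, beside camera with an estimated correlation and fry. Principal components used the 500 most variable genes, centred and not scaled. Differences of components, list scores and distances were tested by exact permutation over all assignments of the libraries, whose smallest two-sided p is 0.00216. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

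The test, the threshold, the lists and the rule for named genes were fixed before the data were examined. The rule named the 12 genes with the largest increase and the 12 with the largest decrease among those past the threshold, without unnamed gene models. It also named the 4 genes of each list with the smallest p, and 16 genes whatever their values, S100a8, S100a9, Il1b, Tnf, Il6, Cxcl1, Cxcl2, Tlr4, Cd14, Ly6c2, Ccr2, Ly6g, Sftpc, Scgb1a1, Il33 and Il1r1. Downward 9 genes passed. The rule gave 210 measured genes, of which the text names the ones it discusses. The lists were neutrophil markers, classical monocyte markers, nonclassical monocyte markers, alveolar macrophage markers, interstitial macrophage markers, dendritic cell markers, B cell markers, plasma cell and immunoglobulin genes, T cell markers, NK and cytotoxic cell genes, regulatory T cell and group 2 innate lymphoid cell genes, mast cell, basophil and eosinophil genes, alveolar type 1 cell markers, alveolar type 2 cell markers, ciliated cell markers, club and goblet cell markers, capillary endothelial markers, arterial, venous and lymphatic endothelial markers, endothelial activation genes, fibroblast and extracellular matrix genes, smooth muscle and pericyte markers, mesothelial markers, cardiac muscle genes, skeletal muscle genes, adipocyte genes, thymocyte genes, lymphoid follicle and chemokine genes, erythrocyte genes, platelet genes, inflammatory cytokine and NF-kB genes, pattern recognition and inflammasome genes, type I interferon response genes, interferon gamma response genes, antigen presentation genes, alternative activation and suppression genes, proliferation genes, complement and coagulation genes, oxidative phosphorylation genes, glycolysis and hypoxia genes, cholesterol and fatty acid synthesis genes, unfolded protein and integrated stress response genes, antioxidant and metallothionein genes, circadian clock genes, glucocorticoid target genes, immediate early genes, heat shock genes, mitochondrially encoded genes and ribosomal protein genes.

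On simulated data of the same size, the same steps recovered 49 of 50 genes raised 2-fold, 40 of 50 raised 1.5-fold, 49 of 50 lowered to 0.5 and 39 of 50 lowered to 0.667. Among 182 calls, 5 were genes left unchanged (2.75%), and 0 genes were called when none was changed. Simulated genes varied independently, so these rates leave out correlation between genes and structure shared by libraries. Changed genes were drawn away from the lowest and the highest mean reads. Genes with at least 10 normalised reads were given the median spread of genes with like means. The rates therefore do not cover genes with few reads or with more than that spread.

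Alternatives set before the data were seen were a fit without the trend, a fit with robust moderation, array quality weights, quantile normalisation, a shift to equal medians, removal of the 25% of genes with the lowest means, a haemoglobin covariate, removal of each library in turn, an exact rank-sum test and other thresholds. For lists they were the estimated correlation, fry and removal of genes shared by lists, and for components 2000 or all genes. Chosen after the data were seen were limma's voom on the recovered reads, for all genes and for genes with at least 10 normalised reads, the removal of 2 libraries together, and a covariate of co-varying genes. Tests of grouping drew 100 of the 462 possible splits of the libraries into 6 and 6. Il6 and other listed genes that are not among the table's genes were not analysed here.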

Results

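RNA of perfused lungs from 12 male C57BL/6 mice was counted by sequencing the 3' ends of polyadenylated transcripts. The survivor group held 6 mice taken 21 days after cecal ligation and puncture (CLP), an operation that leaks gut bacteria into the abdomen and causes sepsis. The other group held 6 mice that had no operation. Each library carried between 3098945 and 5563531 reads assigned to genes, with a mean of 4027923 ± 531274 (SD, n = 6) in CLP survivors and 4183798 ± 746039 (SD, n = 6) in unoperated mice. Total reads did not differ detectably between the groups (exact two-sided permutation p = 0.697). The comparison of the groups asks how the lung transcriptome of survivors of CLP differs from that of unoperated mice. No group had an operation without the puncture. An effect of sepsis therefore cannot be told apart from one of the operation or of selection by survival.

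In the lungs of CLP survivors, single genes of antibody chains, neutrophil granules and monocytes rose, and single genes of heat shock proteins fell. With an estimated inter-gene correlation the list of nonclassical monocyte markers passed (adjusted p = 0.0400), and those of plasma cell and immunoglobulin genes, neutrophil markers, classical monocyte markers and heat shock genes did not (adjusted p = 0.0541, 0.118, 0.144 and 0.0557). The immunoglobulin mu chain gene Ighm stood at 1040.3 ± 364 normalised reads (SD, n = 6) against 416 ± 183 in unoperated mice, a 2.50-fold rise (adjusted p = 0.00920). The neutrophil granule genes Ngp and Camp rose from near 0 in most unoperated lungs to means of 41.7 and 31.1 normalised reads, 12.0-fold and 17.9-fold (adjusted p = 0.00920 for each). Unoperated replicate 5 set the size of these folds. Without it Ngp, with 2 reads left in the unoperated group, was 114-fold higher (95% counting interval 31.3 to 949), and Camp was at least 51.1-fold higher against a floor of 3 reads over the group. Nonclassical monocyte genes such as Treml4 (2.66-fold) and Cx3cr1 (1.57-fold) were higher in 6 of 6 survivors than in any unoperated mouse. The small heat shock protein gene Hspb1 fell 1.85-fold, from 739 ± 133 to 399.8 ± 63.9 normalised reads (SD, n = 6), and Cyp1a1, a detoxifying enzyme gene, fell 2.48-fold.

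In all, 73 of 20858 genes changed at an adjusted p under 0.05, 64 higher and 9 lower in CLP survivors, in limma's moderated test on the deposited log2-scale values. Among the 64 higher genes, 15 belonged to a list of immune cell markers and 2 were unnamed gene models. Median folds were 1.84 for the higher genes and 0.561 for the lower ones. The 2 groups did not overlap for 53 of the 73 genes. Over all genes, 0.897% showed no overlap, against 0.216% by chance. Of 48 gene lists fixed before the data were examined, 35 changed relative to other genes under a preset inter-gene correlation of 0.01, 21 upward and 14 downward. With an estimated correlation 1 of the 35 calls held, that of the nonclassical monocyte markers, so each list that changed is given below with both adjusted p values. By fry 7 lists passed, and 15 list scores passed the exact permutation test after adjustment. The 7 lists that passed fry passed the exact test too. They were the nonclassical monocyte, plasma cell, NK and cytotoxic cell, heat shock, circadian clock, antioxidant and unfolded protein lists. Neutrophil markers passed the exact test alone, and classical monocyte markers neither.

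**Figure D1:**
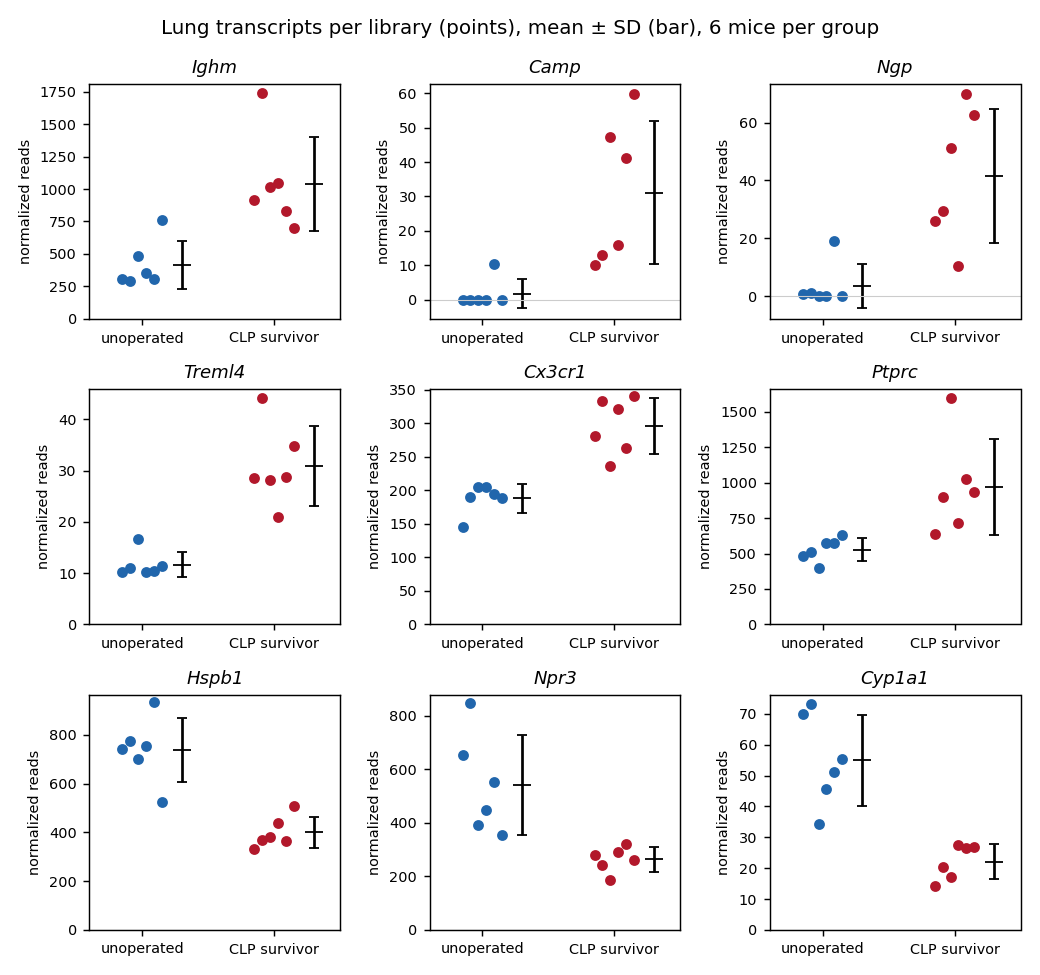
Normalised reads of 9 genes in each library (points) with the group mean and SD (bars), 6 mice per group, each panel with its own linear axis. Ighm, Camp, Ngp, Treml4, Cx3cr1 and Ptprc had higher means in CLP survivors, and Hspb1, Npr3 and Cyp1a1 had lower means. Treml4, Cx3cr1, Ptprc, Hspb1, Npr3 and Cyp1a1 did not overlap between the groups.

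Of 18 measured plasma cell and immunoglobulin genes, 7 rose over all genes tested, and 11 rose and 1 fell when adjusted over the list alone. The list's median difference was 0.49 on the log2 scale (adjusted p = 9.74e-14; adjusted p = 0.0541 with an estimated correlation). Ighm (chromosome 12, 113418558 to 113422730, GRCm38, GENCODE M21) rose by 1.18 ± 0.19 on that scale (SE). The kappa chain gene Igkc rose by 1.19 ± 0.23, from 367 ± 188 to 943 ± 433 normalised reads (SD, n = 6, adjusted p = 0.0308). Ighg3 and Ighg2b, constant regions of switched antibodies, rose 12.4-fold and 5.21-fold (adjusted p = 0.00920 and 0.0260), and 26.0-fold and 12.7-fold without unoperated replicate 6. The lambda genes Iglc1 and Iglc2 rose 2.87-fold and 2.23-fold, and whether reads were assigned to the right lambda gene was not tested. Jchain, which links antibodies into polymers, rose 2.47-fold (adjusted p = 0.0236). Calls of Ighm, Ighg3 and Iglc2 held without each library in turn. Those of Iglc1, Jchain, Ighg2b and Igkc were lost without CLP survivor replicate 2 or unoperated replicate 1, with adjusted p up to 0.0622, 0.0814, 0.0871 and 0.106. The last 3 were lost also without CLP survivor replicate 5 or unoperated replicate 2 or 4, Jchain and Ighg2b without unoperated replicate 3, Ighg2b and Igkc without unoperated replicate 5, and Igkc without CLP survivor replicate 1. Without CLP survivor replicate 2 the list's median was 0.32. Among 16 B cell markers, 0 passed over all genes and 2 rose adjusted over the list alone. Their median was 0.21 (adjusted p = 2.44e-06; adjusted p = 0.287 with an estimated correlation), 0.13 without CLP survivor replicate 2 and 0.33 without unoperated replicate 6. The B cell surface gene Ms4a1 had 134 against 71.2 normalised reads (adjusted p = 0.198).

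Of 21 neutrophil markers, 2 rose over all genes and 12 rose adjusted over the list alone, with a median difference of 0.34 (adjusted p = 1.02e-13; adjusted p = 0.118 with an estimated correlation). Ngp (chromosome 9, 110419747 to 110423012) and Camp (chromosome 9, 109847379 to 109849617), which encode proteins of neutrophil granules, passed also without each library in turn. Unoperated replicate 5 had 10.4 normalised reads of Camp, and the other 5 unoperated libraries had 0. S100a8 and S100a9, abundant alarmin genes of neutrophils, differed by 1.40 and 1.53 without passing (adjusted p = 0.141 and 0.0838), except without unoperated replicate 5 (adjusted p = 0.0209 and 0.0149). S100a8 had 3098 ± 1619.6 normalised reads in CLP survivors (SD, n = 6). The chemokine receptor gene Cxcr2 (2.66-fold, adjusted p = 0.0698) and the schlafen gene Slfn4 (3.41-fold, adjusted p = 0.0696) did not pass either, except without the same library (adjusted p = 0.0213 and 0.0331) and, for Cxcr2, without CLP survivor replicate 1 (adjusted p = 0.0384). Ly6g, the usual surface marker of neutrophils, had 15.1 against 3.48 normalised reads (adjusted p = 0.253).

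Of 10 nonclassical monocyte markers, 3 rose over all genes, and 5 rose and 1 fell adjusted over the list alone. Their median was 0.32 (adjusted p = 5.11e-06; adjusted p = 0.0400 with an estimated correlation). Treml4 (chromosome 17, 48264295 to 48275360), a receptor of the TREM family, rose from 11.6 ± 2.48 to 30.9 ± 7.83 normalised reads (SD, n = 6, adjusted p = 0.00920). Cx3cr1, the fractalkine receptor, rose from 188 ± 22 to 296 ± 42.3 (adjusted p = 0.0142), and without CLP survivor replicate 2 it had an adjusted p of 0.0538. Itgal, the alpha chain of the integrin LFA-1, rose 1.67-fold (adjusted p = 0.0221), and its call was lost without any 1 of CLP survivor replicate 2 and unoperated replicates 1 to 4 (adjusted p up to 0.0699). Of 12 classical monocyte markers, 2 rose over all genes, and 6 rose and 2 fell adjusted over the list alone, with a median of 0.30 (adjusted p = 7.46e-05; adjusted p = 0.144 with an estimated correlation). The 2 were Plac8 (1.84-fold, adjusted p = 0.0203) and Ifitm6 (2.43-fold, adjusted p = 0.0218), which reached adjusted p of 0.0608 without CLP survivor replicate 5 and 0.0622 without CLP survivor replicate 2. The call of Plac8 was lost also without unoperated replicate 1, 3 or 4, and that of Ifitm6 without CLP survivor replicate 5 or 6 or unoperated replicates 1 to 4. Ly6c2 and Ccr2, which mark classical monocytes, had folds of 1.45 and 1.28 (adjusted p = 0.285 and 0.544). Ptprc, the leukocyte surface phosphatase CD45, rose 1.84-fold, from 528 ± 81.4 to 969 ± 341 normalised reads (SD, n = 6, adjusted p = 0.0423). Its call held without CLP survivor replicates 1, 3 or 4 or unoperated replicate 6 and was lost without any 1 of the other 8 libraries, with adjusted p up to 0.125 without unoperated replicate 1.

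Lists of tissue macrophage genes did not pass upward. The 16 alveolar macrophage markers had a median of -0.058, with 14 below 0 and 0 past the test singly (adjusted p = 0.0275; adjusted p = 0.361 with an estimated correlation). This list's call was lost without CLP survivor replicate 2, 3 or 5 or unoperated replicate 2 or 5 (medians -0.050, -0.048, -0.035, -0.048 and -0.043), and the median was -0.090, -0.088 and -0.096 without CLP survivor replicates 1, 4 and 6. The 14 interstitial macrophage markers did not pass (median 0.058, adjusted p = 0.145). Among 15 dendritic cell markers, 0 passed over all genes and 1 rose adjusted over the list alone (median 0.094, adjusted p = 0.0249; adjusted p = 0.287 with an estimated correlation). That call was lost without CLP survivor replicate 2 or 6 or unoperated replicate 2 or 4 (medians 0.058, 0.083, 0.079 and 0.062). Ccr7, the homing receptor of migrating dendritic cells, had 47.9 against 22.6 normalised reads (adjusted p = 0.0604), and passed without CLP survivor replicate 4 or unoperated replicate 6 (adjusted p = 0.0418 and 0.0129).

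Among lymphocyte genes, 1 survivor library carried a large share of the T cell signal. In CLP survivor replicate 3 the recombinase gene Rag1, expressed by developing lymphocytes, had 2159.8 normalised reads, against at most 17.1 in any other library. All 20 T cell markers were above 0, with 0 past the test over all genes and 1 higher adjusted over the list alone. Their median of 0.54 (adjusted p = 7.63e-10; adjusted p = 0.287 with an estimated correlation) was 0.20 without that library. The thymocyte genes likewise had a median of 0.51 (adjusted p = 0.000108; adjusted p = 0.361 with an estimated correlation), and 0.12 without it, with 0 of 11 past the test over all genes and 0 adjusted over the list alone. With 2 members that had no read in the unoperated group set to the log2 of their lower-bound fold, the thymocyte median was 0.74. That value mixes log2 folds of reads with VST differences and cannot be compared with 0.51. The 31 proliferation genes had a median of 0.28 (adjusted p = 3.81e-10; adjusted p = 0.299 with an estimated correlation), and 0.095 without the same library, with 0 past the test over all genes or adjusted over the list alone. At the preset correlation the T cell, thymocyte and proliferation lists still passed without that library (adjusted p = 4.32e-12, 0.00186 and 4.88e-07). Their scores without it had unadjusted exact permutation p of 0.0303, 0.00866 and 0.00216. An estimated correlation was not run without it. With all libraries, proliferation scores of all survivors lay above those of all unoperated mice (lowest 0.041 against highest 0.035). Mki67, a marker of cycling cells, had 138 against 37.0 normalised reads (adjusted p = 0.337). Without CLP survivor replicate 3 it had 65.8 against 37.0 and passed (adjusted p = 0.0297). Of 20 NK and cytotoxic cell genes, 0 passed over all genes and 9 rose adjusted over the list alone, and all 20 were above 0 (median 0.18, adjusted p = 2.41e-11; adjusted p = 0.0557 with an estimated correlation). The transcription factor gene Eomes had 10.8 against 3.08 normalised reads (adjusted p = 0.0604). Ifng had 11 reads in the survivor group and 0 in the unoperated group, at least 3.48-fold higher against a floor of 3 reads over the group, by counting error alone (adjusted p = 0.166). Without CLP survivor replicate 4 both genes passed (adjusted p = 0.0418 and 0.0413). The 10 regulatory T cell and group 2 innate lymphoid cell genes had a median of 0.12 (adjusted p = 0.00204; adjusted p = 0.221 with an estimated correlation), with 0 past over all genes and 1 higher adjusted over the list alone. That median was 0.069 without CLP survivor replicate 3 and 0.18 without CLP survivor replicate 4.

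Among 12 mast cell, basophil and eosinophil genes, 1 rose over all genes and 3 rose adjusted over the list alone (median 0.091, adjusted p = 0.0116; adjusted p = 0.152 with an estimated correlation). This gene was Ccr3, the eotaxin receptor, at 21.3 ± 6.68 against 6.74 ± 2.20 normalised reads (SD, n = 6, adjusted p = 0.0158), with an adjusted p of 0.0622 without CLP survivor replicate 2, its call being lost also without unoperated replicate 1. The 11 lymphoid follicle and chemokine genes had a median of 0.16 (adjusted p = 0.000300; adjusted p = 0.152 with an estimated correlation), with 0 past over all genes and 4 higher adjusted over the list alone. That median was 0.087 without CLP survivor replicate 2 and 0.10 without unoperated replicate 1. Cxcl13, the B cell attracting chemokine, had 94.8 against 46.1 normalised reads (adjusted p = 0.0696), and passed without unoperated replicate 6 (adjusted p = 0.00965). Of 13 platelet genes, 1 rose over all genes and 4 rose adjusted over the list alone, and all 13 were above 0 (median 0.16, adjusted p = 1.99e-06; adjusted p = 0.144 with an estimated correlation). Ppbp, a chemokine stored in platelet granules, rose 1.74-fold (adjusted p = 0.0423), and its call held without CLP survivor replicates 3 or 4 and was lost without any 1 of the other 10 libraries, with adjusted p up to 0.125 without unoperated replicate 1. All 12 erythrocyte genes were above 0, with 0 past over all genes and 2 higher adjusted over the list alone (median 0.26, adjusted p = 5.94e-07; adjusted p = 0.144 with an estimated correlation). Hbb-bt, an adult beta globin gene, had 3525 against 2007 normalised reads (adjusted p = 0.448).

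Of 30 type I interferon response genes, 2 rose over all genes and 5 rose adjusted over the list alone, with a median of 0.14 (adjusted p = 3.19e-08; adjusted p = 0.144 with an estimated correlation). The antiviral genes Rsad2 and Mx1 rose 1.92-fold and 1.84-fold (adjusted p = 0.0155 and 0.0308) and exceeded every unoperated library in 6 of 6 survivors. Adjusted p was 0.0539 for Rsad2 without unoperated replicate 1, and up to 0.0811 for Mx1 without CLP survivor replicate 5. The call of Mx1 held without CLP survivor replicates 3 or 4 or unoperated replicate 6 and was lost without any 1 of the other 9 libraries. Among 27 interferon gamma response genes 0 passed over all genes or adjusted over the list alone (median 0.093, adjusted p = 0.0388; adjusted p = 0.660 with an estimated correlation). The median turned to -0.058 without CLP survivor replicate 6, where the chemokine gene Cxcl9 had 157 normalised reads. The list's call was lost there, and also without unoperated replicates 1, 3, 4 or 5 (medians 0.045, 0.071, 0.078 and 0.076). The 24 antigen presentation genes rose as a list, with a median of 0.071 (adjusted p = 0.0249; adjusted p = 0.560 with an estimated correlation) and -0.031 without CLP survivor replicate 6, and 0 past over all genes or adjusted over the list alone. Without unoperated replicates 1, 4 or 5 their call was lost (medians 0.049, 0.047 and 0.072), and the median was 0.12, 0.11 and 0.11 without CLP survivor replicate 3, unoperated replicate 2 and unoperated replicate 6.

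Of 25 inflammatory cytokine and NF-kB genes, 0 passed over all genes and 4 rose adjusted over the list alone (median 0.12, adjusted p = 2.44e-06; adjusted p = 0.118 with an estimated correlation). The acute phase gene Saa3 had 48.3 against 7.84 normalised reads (adjusted p = 0.0711; it passed without CLP survivor replicate 1 at 0.0474), and Il1b had 274 against 111 (adjusted p = 0.169). Tnf, Cxcl1 and Cxcl2 stayed below 10 normalised reads in both group means (adjusted p = 0.451, 0.878 and 0.604), and Il6 was not among the genes of the file. Among 29 pattern recognition and inflammasome genes, 0 passed over all genes and 7 rose adjusted over the list alone, with 26 above 0 (median 0.10, adjusted p = 1.49e-06; adjusted p = 0.118 with an estimated correlation). Clec4e, a receptor for microbial glycolipids, had 46.7 against 18.8 normalised reads (adjusted p = 0.112), and passed without CLP survivor replicate 1 or unoperated replicate 5 (adjusted p = 0.0450 and 0.0336). The endotoxin receptor genes Tlr4 and Cd14 differed by 0.027 ± 0.074 and 0.015 ± 0.11 (log2, SE; adjusted p = 0.950 and 0.983). The interleukin 1 receptor gene Il1r1 differed by -0.012 ± 0.082, and the alarmin gene Il33 by -0.31 ± 0.12 (adjusted p = 0.982 and 0.408). The 25 complement and coagulation genes did not pass as a list (median -0.10, adjusted p = 0.0968; it passed without CLP survivor replicate 6 at 0.00676 and without unoperated replicate 4 at 0.0410), with 1 higher over all genes, and 2 higher and 1 lower adjusted over the list alone. F5, coagulation factor V, rose 2.20-fold, from 39.7 ± 8.98 to 87.2 ± 19.5 normalised reads (SD, n = 6, adjusted p = 0.00920), and its call held without each library in turn. The 17 alternative activation and suppression genes did not pass (median -0.0052, adjusted p = 0.698).

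Of 16 heat shock genes, 3 fell over all genes and 11 fell adjusted over the list alone, with a median of -0.31 (adjusted p = 9.74e-14; adjusted p = 0.0557 with an estimated correlation). Hspb1 (chromosome 5, 135887919 to 135889563) had the largest fall of the 3, by 0.76 ± 0.11 on the log2 scale (SE, adjusted p = 0.00920). The cytosolic chaperone genes Hsp90aa1 and Hsp90ab1 fell 1.41-fold and 1.35-fold (adjusted p = 0.0328 and 0.0435), and these 3 genes were lower in 6 of 6 survivors than in any unoperated mouse. Hspb1 passed without each library in turn, and the calls of Hsp90aa1 and Hsp90ab1 held without CLP survivor replicate 3 or unoperated replicate 6. The call of Hsp90aa1 held also without CLP survivor replicate 4, and both were lost without any 1 of the other 9 libraries, with adjusted p up to 0.106 and 0.140 without unoperated replicate 1. Hsph1, a chaperone of the same response, had 168 ± 16.1 against 312 ± 109 normalised reads (SD, n = 6, adjusted p = 0.0711), and passed without unoperated replicate 6 (adjusted p = 0.0105). The 20 unfolded protein and integrated stress response genes fell as a list (median -0.15, adjusted p = 1.06e-05; adjusted p = 0.118 with an estimated correlation), with 0 past over all genes or adjusted over the list alone. Hspa5, the main chaperone of the endoplasmic reticulum, had 2300.2 against 2907 normalised reads (adjusted p = 0.285).

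Of 20 antioxidant and metallothionein genes, 1 fell both over all genes and adjusted over the list alone (median -0.18, adjusted p = 8.65e-06; adjusted p = 0.0920 with an estimated correlation). It was Cyp1a1 (chromosome 9, 57687928 to 57703824), the classic target of the aryl hydrocarbon receptor, which fell 2.48-fold, from 55.0 ± 14.8 to 22.1 ± 5.70 normalised reads (SD, n = 6, adjusted p = 0.00920). The 20 circadian clock genes fell as a list (median -0.17, adjusted p = 0.000459; adjusted p = 0.0541 with an estimated correlation), with 0 past over all genes and 1 lower adjusted over the list alone. The clock repressor gene Nr1d1 had 176 ± 26.9 against 247 ± 33.0 normalised reads (SD, n = 6, adjusted p = 0.0714) and was lower in 6 of 6 survivors than in any unoperated mouse. It passed without CLP survivor replicate 1 (adjusted p = 0.0474). The 16 glucocorticoid target genes fell as a list (median -0.20, adjusted p = 0.0138; adjusted p = 0.361 with an estimated correlation), with 0 past over all genes or adjusted over the list alone. Their call was lost without CLP survivor replicate 6 or unoperated replicate 5 (medians -0.17 and -0.14). The 25 immediate early genes did not pass (median 0.0049, adjusted p = 0.310), except without CLP survivor replicate 1 (median 0.087, adjusted p = 0.0299).

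The other genes that fell belonged to no fixed list. Npr3 (chromosome 15, 11839896 to 11907287) fell by 0.81 ± 0.15 on the log2 scale, from 541 ± 186 to 263 ± 46.9 normalised reads (SD, n = 6, adjusted p = 0.0218), with an adjusted p of 0.0756 without unoperated replicate 1, its call being lost also without CLP survivor replicate 2 or 6. Hspa12b, a divergent heat shock protein gene of endothelial cells, fell 1.48-fold (adjusted p = 0.0445). The adaptor gene Grb7 fell 1.48-fold (adjusted p = 0.0308) and the transcriptional regulator gene Mn1 fell 1.78-fold (adjusted p = 0.0458). Wfdc12, a gene of the whey acidic protein family, had 0 reads in all survivors and 11 over the unoperated group, at least 3.57-fold lower against a floor of 3 reads over the group (adjusted p = 0.0308). Leaving out single libraries ended these calls, with adjusted p up to 0.131 for Hspa12b without CLP survivor replicate 2 and 0.0924 for Grb7 without CLP survivor replicate 5. For Mn1 it was up to 0.147 without unoperated replicate 1, and for Wfdc12 up to 0.0812 without unoperated replicate 2. All 4 calls held without CLP survivor replicate 4 and were lost without CLP survivor replicates 2 or 5 or unoperated replicates 1 to 5. Without unoperated replicate 6 that of Mn1 alone was lost, without CLP survivor replicate 6 those of Grb7, Mn1 and Wfdc12, without CLP survivor replicate 1 those of Hspa12b, Mn1 and Wfdc12, and without CLP survivor replicate 3 those of Hspa12b and Mn1.

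All 18 alveolar type 2 cell markers were below 0, with a median of -0.17 (adjusted p = 2.37e-08; adjusted p = 0.144 with an estimated correlation), 0 past over all genes and 1 lower adjusted over the list alone. The surfactant gene Sftpb had 8505 ± 1321 against 11307 ± 1293 normalised reads (SD, n = 6, adjusted p = 0.155), and Sftpc had 39885 ± 4862 against 44954 ± 3704 (adjusted p = 0.649). All 18 ciliated cell markers were below 0 too (median -0.12, adjusted p = 2.31e-06; adjusted p = 0.152 with an estimated correlation), with 0 past over all genes and 3 lower adjusted over the list alone. Rsph1, a radial spoke gene of cilia, had 52.5 against 77.7 normalised reads (adjusted p = 0.0810). Of 17 club and goblet cell markers, 15 were below 0, 0 passed over all genes and 1 fell adjusted over the list alone (median -0.12, adjusted p = 2.45e-05; adjusted p = 0.144 with an estimated correlation). That median was -0.18 without CLP survivor replicate 2 and -0.20 without unoperated replicate 5. Cyp2f2, a cytochrome of club cells, had a 1.28-fold lower mean (adjusted p = 0.163), and the club cell secretory protein gene Scgb1a1 had a mean 0.821 times that of unoperated mice (adjusted p = 0.544). The 16 alveolar type 1 cell markers did not pass (median -0.0077, adjusted p = 0.648).

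Vascular and stromal marker lists had medians near 0. The 20 capillary endothelial markers had a median of 0.026 (adjusted p = 0.296), and 0.097 without CLP survivor replicate 3 (adjusted p = 0.000934), where the list passed upward. The 15 arterial, venous and lymphatic endothelial markers and the 15 endothelial activation genes did not pass (adjusted p = 0.395 and 0.940), and the median of the latter was below 0 while its test pointed upward. The 31 fibroblast and extracellular matrix genes fell as a list (median -0.077, adjusted p = 0.0488; adjusted p = 0.560 with an estimated correlation), with 0 past over all genes or adjusted over the list alone. Without CLP survivor replicate 3 their median was 0.0073 and the call was lost, as it was without CLP survivor replicate 4 and unoperated replicates 1, 2, 5 and 6 (medians -0.071, -0.053, -0.042, -0.066 and -0.024). The 17 smooth muscle and pericyte markers did not pass (median -0.077, adjusted p = 0.101), except without CLP survivor replicate 2, CLP survivor replicate 4 or unoperated replicate 2 (adjusted p = 0.0179, 0.0472 and 0.0477). Of 11 mesothelial markers, 10 were below 0 and 0 passed over all genes or adjusted over the list alone (median -0.098, adjusted p = 0.00690; adjusted p = 0.287 with an estimated correlation). Their median was -0.16 without CLP survivor replicate 6.

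Of the metabolic lists, the 29 oxidative phosphorylation genes fell as a list (median -0.059, adjusted p = 0.00676; adjusted p = 0.560 with an estimated correlation), with 0 past over all genes or adjusted over the list alone. Their call was lost without CLP survivor replicate 1 or 5 or unoperated replicate 1 or 3 (medians -0.038, -0.038, -0.051 and -0.021). Their median was -0.12, -0.10 and -0.094 without CLP survivor replicate 3 and unoperated replicates 2 and 5. The 25 glycolysis and hypoxia genes and the 25 cholesterol and fatty acid synthesis genes did not pass (adjusted p = 0.753 and 0.129), except the latter without CLP survivor replicate 1 (median -0.038, adjusted p = 0.0202). The mitochondrially encoded and ribosomal protein lists were set as measures of RNA quality, not of metabolism, and RNA quality was not tested as a cause. The 13 mitochondrially encoded genes fell as a list (median -0.11, adjusted p = 0.00330; adjusted p = 0.287 with an estimated correlation), with a median of -0.072 without CLP survivor replicate 1. The 34 ribosomal protein genes rose as a list (median 0.064, adjusted p = 0.0442; adjusted p = 0.605 with an estimated correlation), with a median of 0.10, -0.0035 and 0.11 without CLP survivor replicates 1, 3 and 5. That call was lost without CLP survivor replicates 3, 4 or 6 or unoperated replicates 1, 2, 4 or 5, with adjusted p from 0.0543 to 0.948. In both of these lists 0 genes passed over all genes or adjusted over the list alone.

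Some gene lists set for neighbouring tissues marked single libraries, and the origin of their RNA was not tested. The 15 cardiac muscle genes fell as a list (median -0.13, adjusted p = 0.0138; adjusted p = 0.560 with an estimated correlation), with 0 past over all genes or adjusted over the list alone. That fall rested on unoperated replicate 3, in which the cardiac myosin gene Myh6, chosen after its values were seen, had 361 normalised reads, and the median without it was 0.053. The call was lost also without CLP survivor replicates 1 and 6 and unoperated replicate 1 (medians -0.089, -0.052 and -0.076), and the median was -0.24 without unoperated replicate 2. The 7 skeletal muscle genes did not pass (median 0.092, adjusted p = 0.10), except without CLP survivor replicate 1, CLP survivor replicate 6 or unoperated replicate 3 (adjusted p = 0.0202, 0.0485 and 0.0497). The 15 adipocyte genes did not pass (median -0.086, adjusted p = 0.0503), except without any 1 of CLP survivor replicates 2 and 3 and unoperated replicates 2, 4 and 5 (adjusted p between 0.00146 and 0.0294).

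**Figure D2:**
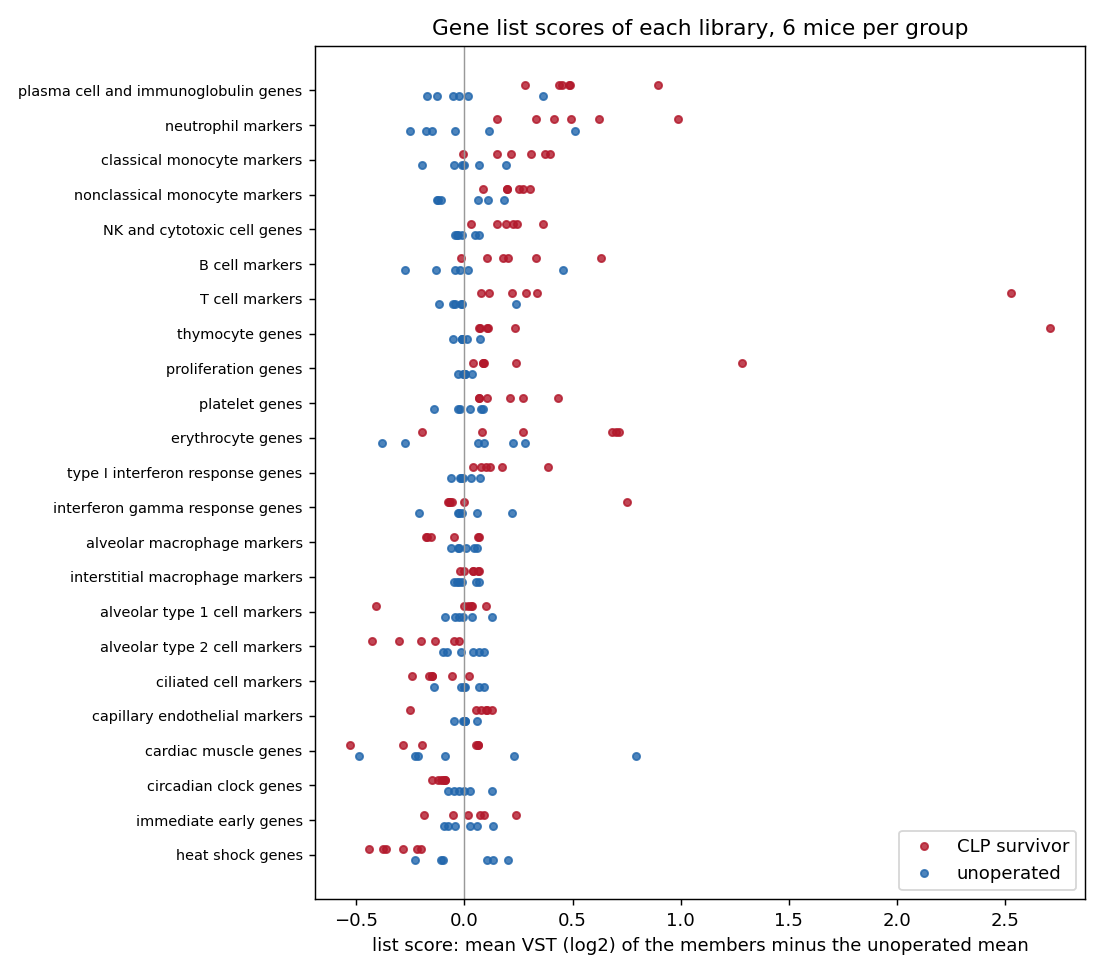
Score of 23 of the 48 gene lists in each library (points), the mean log2-scale value of the list's genes minus the mean of the unoperated group, with 6 mice per group. CLP survivor replicate 3 stood apart in the T cell, thymocyte and proliferation lists with scores of 2.53, 2.71 and 1.28, and CLP survivor replicate 6 in the interferon gamma list with 0.75. The 6 survivors all lay below the 6 unoperated mice for the circadian clock genes, and above them for the proliferation genes.

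The first principal component of the 500 most variable genes, with 52.3% of the variance, differed by 7.55 between the group means (exact two-sided permutation p = 0.00216, the smallest that the design allows). Its genes with the largest loadings included Rag1 and Themis, and CLP survivor replicate 3 scored 24.5 against at most 1.10 in any other library. Without that library the first component differed by 1.39 (exact permutation p = 0.667) and the second by 7.12 (exact permutation p = 0.00433). With all libraries the second component held 14.4% of the variance and differed by 0.57 (exact permutation p = 0.816). Distances among CLP survivors were 1.24 times those among unoperated mice (exact permutation p = 0.942), and 0.760 times without CLP survivor replicate 3 (exact permutation p = 0.0498).

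**Figure D3:**
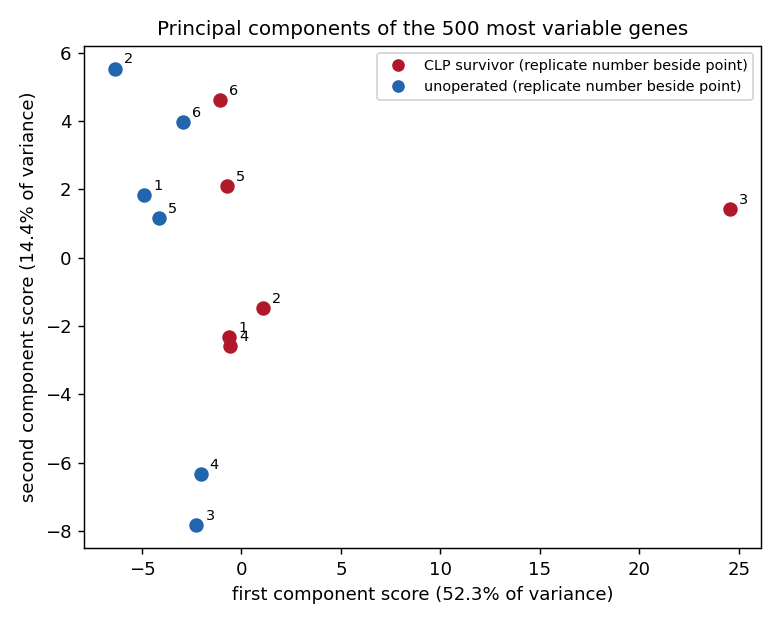
Scores of the 12 libraries on the first and second principal components of the 500 most variable genes, in units of the log2-scale values, with the replicate number beside each point. CLP survivor replicate 3 lay at 24.5 on the first component, and the other survivors lay between -1.06 and 1.10, above all unoperated libraries.

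The count of 73 genes was 22, 31 and 34 without CLP survivor replicates 2, 5 and 6, and 21, 31, 31 and 27 without unoperated replicates 1 to 4. It was 36 without both CLP survivor replicate 3 and unoperated replicate 3, the libraries rich in thymic and cardiac genes, a choice made after the data were seen.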

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

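The tests of thymic RNA, of more blood-borne myeloid cells, of time of day and of handling stress were chosen after the results they bear on were seen. So were those of dilution, of a gradient shared by libraries of both groups and of the count with the covariate of co-varying genes. The tests of residual blood and of other splits were set before.

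Other splits of the 12 libraries tested whether the counts could arise without the operation. Of 100 splits into 6 and 6, 2 gave at least as many genes as the real split's 73, the real one included. A count that high was thus rare among random groupings but not excluded, as the highest other split gave 298. That split set CLP survivors 1 to 4 and unoperated mice 3 and 4 against the rest, shared 0 of the 73 genes, and parted the libraries by a set of co-varying genes (Sox18, Scnn1g, Adam9, Rpl17-ps3 and Rpl22l1, mean VST 7.27 against 8.62), which points to a structure of the samples other than the operation. With these genes as a covariate the real split gave 104 genes, 70 of them among the 73. For lists, 1 of the 100 splits, the real one, gave as many as 35. A count that high was rare there too, although the highest other split gave 32. The other splits gave a median of 0 genes but of 19 lists, so the 35 lists are to be read against about that many and not against 0.

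The first pattern weighed is the rise of 64 genes in CLP survivors, leukocyte and immunoglobulin genes among them. Without the library of CLP survivor 3, rich in thymic genes, the 64 higher genes kept 97.3% of their median difference (lower quartile 92.4%). Of them 50 stayed past the threshold. A gene carried by 1 library seldom passes, so a high share was likely for genes picked this way and does not decide about thymic RNA. The T cell list, not picked by its calls, went from a median of 0.54 to 0.20 without that library. With the haemoglobin genes as a covariate the median difference was 0.48 before and 0.48 after (101%), with a lower quartile of 90.8% kept. Genes picked for differences large against their spread within groups can follow a covariate only weakly there. A high share was thus likely here too, and residual blood with its red cells was not decided. Of the 64 genes 5 still passed, and as the median standard error grew from 0.089 to 0.098 while some differences shrank, the shares of lost precision and of smaller differences in the lost calls were not separated. A larger share of blood-borne myeloid cells in survivor lungs, whether in tissue or held in vessels, stays open and was not decided, because the contrast of neutrophil and monocyte scores with resident macrophage scores (0.34, exact permutation p = 0.00649; 0.00866 without CLP survivor 3) restates list differences already seen.

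The second pattern is the fall of the heat shock list (adjusted p = 0.0557 with an estimated correlation). With the co-varying genes as a covariate 94.5% of the median fall was kept, which argues against the gradient they follow as the whole cause. Whether that gradient is technical was not tested. Less handling stress at collection stays open, because the immediate early gene score differed by 0.029 ± 0.069 (SE), against 0.31 lower in the heat shock score, while the glucocorticoid target list went down too (median -0.20, adjusted p = 0.0138; 0.361 with an estimated correlation; score difference -0.12, exact permutation p = 0.249). Another time of day at collection cannot be told apart from the operation, because the labels give no collection times and the clock genes differed between the groups (output arm minus Arntl arm -0.38, exact permutation p = 0.0130). Within groups the clock contrast did not follow the heat shock score detectably (Pearson r = -0.0888, permutation p = 0.816, Spearman rho = -0.0699, permutation p = 0.845, 12 libraries; r = -0.27 without the 2 farthest), and an effect of the operation itself remains open too.

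The third pattern is the lower level of the alveolar type 2 list (adjusted p = 0.144 with an estimated correlation). Mere dilution by RNA of other cells would have lowered all lists of lung structure by 1 factor, and on log2 normalised reads the type 2 genes differed from the mean of the 8 other lists by -0.10 (exact permutation p = 0.139; 0.167 without CLP survivor 3). Taken singly, by exact permutation, the gap passed with and without that library for 1 of the 8, the capillary list (-0.25, Holm p = 0.0173 both ways), which itself passed upward without it, while the gap to alveolar type 1 genes was -0.16 (Holm p = 0.0758; 0.0173 without it) and those to ciliated and to club and goblet genes were 0.041 and -0.010. Dilution therefore cannot be told apart from a change in the type 2 genes themselves, because some of the other lists were lower alike and some were not. Thymic RNA in the library of CLP survivor 3 remains open for part of it, since 68.0% of the median fall was kept without that library, and a loss of type 2 cells and a lower output per cell were not tested.

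Of 96 groups of 6 list scores, 13 held a library far from the others, against about 4.8 that chance gives at 1 in 20 if lists were independent, and 6 of these libraries were CLP survivor 3. Outlying values of single genes follow too, but those genes are the ones named in the text, some because of their values, so their number has no fair comparison with chance. In CLP survivor 3 the first component scored 24.5, and list scores were 2.53 for T cell markers, 2.71 for thymocyte genes, 1.28 for proliferation genes, 0.49 for skeletal muscle genes, -0.41 for alveolar type 1 cell markers and -0.25 for capillary endothelial markers. Normalised reads in that library were 2159.8 for Rag1, 539 for Themis and 497 for Mki67.

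In CLP survivor 6 the interferon gamma response score was 0.75 and the antigen presentation score 0.49, with 157 normalised reads of Cxcl9. In CLP survivor 2 the plasma cell and immunoglobulin score was 0.89 and the lymphoid follicle score 0.48. CLP survivor 5 had 143 normalised reads of Slfn4. Unoperated mouse 6 had a plasma cell and immunoglobulin score of 0.36, a T cell score of 0.24 and a lymphoid follicle score of 0.33, with 99.6 normalised reads of Ighg2b, 139 of Jchain and 96.2 of Cxcl13. Unoperated mouse 5 had 10.4 normalised reads of Camp and 19.0 of Ngp, unoperated mouse 3 had 16.6 of Treml4 and 361 of Myh6, and unoperated mouse 1 had 146 of Cx3cr1.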

How the results depend on the processing

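Voom on the recovered reads, the removal of 2 libraries together and the covariate of co-varying genes were chosen after the data were seen, and the other alternatives before. The 73 genes changed (64 higher, 9 lower) stayed within 1.5 times, at 59 to 104, without the trend, with robust moderation, with quantile normalisation, with equal medians, without the 25% of genes with the lowest means, with voom and with the co-varying covariate. The median of all genes shifted by -0.0051 and -0.015 under the 2 normalisations. Array quality weights gave 129 (112 and 17), the haemoglobin covariate 7 (6 and 1), and the removal of CLP survivor replicate 3 with unoperated replicate 3 gave 36 (29 and 7). Thresholds of 0.10, 0.01 and 0.05 with a difference of at least 0.5 gave 147 (124 and 23), 17 (15 and 2) and 32 (29 and 3). The exact rank-sum test gave 0, 0 and 0 at the adjusted threshold and 1688 genes at an unadjusted p under 0.05, against 2001 with limma, because its smallest p is too coarse for 20858 tests.

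Leaving out 1 library gave 21 to 95 genes changed, 19 to 85 higher and 2 to 10 lower. Counts over 1.5 times smaller were 22, 31 and 34 without CLP survivor replicates 2, 5 and 6, and 21, 31, 31 and 27 without unoperated replicates 1, 2, 3 and 4. Of 29 named genes past the threshold, 9 passed without each library in turn: Ighm, Ngp, Camp, Ighg3, Iglc2, Hspb1, Cyp1a1, Treml4 and F5. Of 5006 comparisons of 210 named genes, 0 changed sign with a call in either fit, 215 fell short of the threshold and 46 passed it. Sign changes of genes past the threshold in neither fit were not counted. The 35 lists numbered 29 to 36 without 1 library, 1 with an estimated correlation, 7 with fry and 30 to 35 under the other settings run, and 26 passed without each library in turn. The cardiac list ranged from -0.24 to 0.053 without 1 library and was 0.056 without both libraries. The interferon gamma list ranged from -0.058 to 0.13, the antigen presentation list from -0.031 to 0.12, and the oxidative phosphorylation list was 0.036 with the haemoglobin covariate. The first component difference ranged from 1.39 to 8.54 and the distance ratio from 0.760 to 1.36 without 1 library, the low ends without CLP survivor replicate 3. Where no cause is given, the cause was not tested. Robust moderation was not run for lists, as camera has no such option. Depth limits genes under 10 normalised reads, where 1 read in the shallowest library adds 0.25 to the value.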

Other observations

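The genes of this part were chosen after their values were seen, and no explanation was tested for them. Those named up to Ifi209 are single genes outside the fixed lists that passed the threshold upward in CLP survivors, not tested as a group. The adhesion receptor gene Adgre4 rose 2.69-fold, from 29.1 ± 8.82 to 78.2 ± 21.7 normalised reads (SD, n = 6, adjusted p = 0.00920). The lectin receptor genes Clec4a1 and Clec4a3 rose 2.06-fold and 1.64-fold (adjusted p = 0.0149 and 0.00920). Fcgr4, a receptor for antibody of the IgG class, rose 1.80-fold, and Fcer1g, the signalling chain shared by such receptors, rose 1.48-fold (adjusted p = 0.0474 and 0.0499). Mmp25, a membrane-anchored protease of leukocytes, rose 2.80-fold (adjusted p = 0.0149). Of these, Adgre4, Clec4a1, Clec4a3, Fcgr4 and Mmp25 were higher in 6 of 6 survivors than in any unoperated mouse. Calls of Adgre4, Clec4a3 and Mmp25 held without each library in turn. That of Clec4a1 was lost without CLP survivor replicate 2 (adjusted p = 0.0580). Adjusted p reached 0.146 for Fcgr4 and 0.151 for Fcer1g without unoperated replicate 1. The call of Fcgr4 held without CLP survivor replicate 3 or unoperated replicates 2 or 5 alone, that of Fcer1g without CLP survivor replicate 1 or unoperated replicate 5 alone.

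Itga4, the alpha 4 integrin chain, rose 1.87-fold (adjusted p = 0.00920), and Pou2f2, a transcription factor of B cells and myeloid cells, rose 2.14-fold (adjusted p = 0.00920). The GTPase gene Rac2 and its activator Dock2 rose 1.99-fold and 1.78-fold (adjusted p = 0.0240 and 0.0218). Cybb, the catalytic subunit of the phagocyte oxidase, rose 1.58-fold (adjusted p = 0.0474). The interferon-inducible genes Ifi206 and Ifi209 rose 2.16-fold and 1.67-fold (adjusted p = 0.0169 and 0.0218), although reads of these related copies can be assigned to either. Calls of Itga4 and Pou2f2 held without each library in turn. Those of Rac2, Dock2 and Ifi209 were lost without CLP survivor replicates 2 or 5 or unoperated replicates 1, 3 or 4, with adjusted p up to 0.0814, 0.0772 and 0.0622. Those of Rac2 and Dock2 were lost also without unoperated replicate 2, and those of Dock2 and Ifi209 without CLP survivor replicate 6. Ifi206 reached 0.0622, its call being lost without CLP survivor replicate 2 or unoperated replicate 1. Cybb reached 0.150 without CLP survivor replicate 2, and its call held without CLP survivor replicates 3 or 4 or unoperated replicate 5 alone.

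A set of 498 genes followed the mean of Sox18, Scnn1g, Adam9, Rpl17-ps3 and Rpl22l1 across libraries of both groups, 474 upward and 24 downward. Of the 464 with at least 10 normalised reads and an annotated kind, 32 were pseudogenes (6.90%), against 1.99% of 13853 such genes (Fisher's exact p = 7.95e-10). That test takes genes as independent, while these were picked for varying together, so its p overstates the evidence. Rpl17-ps3, among the genes of the mean, is itself a pseudogene, which may favour others. The groups did not differ detectably in that mean (difference -0.39, exact permutation p = 0.405).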
